A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

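The 12 samples came from Saccharomyces cerevisiae strains derived from the xylose-fermenting strain MT8-1X, each measured on 1 single-colour Agilent expression array with Cy3-labelled total RNA. A control strain, a strain labelled TAL and a strain labelled TAL-ADH were each exposed for 6 h to 0 or 70 mM furfural, an aldehyde that inhibits fermentation of plant hydrolysates, with 2 runs in each of the 6 groups. The labels do not say whether the 2 runs of a group were separate cultures, so every p-value here measures only the spread between these samples, which may be technical. That TAL stands for the yeast transaldolase gene TAL1 and ADH for the alcohol dehydrogenase gene ADH1 is an assumption; the labels do not name the introduced genes.

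Per the file headers, the deposited scanner files hold the intensity of each spot, background-subtracted and spatially detrended within its array by Agilent Feature Extraction 10.1.1.1 and not normalized between arrays. They also hold the raw median intensity of each spot and of its local background, with marks for spots well above background, saturated or uneven. The deposited table of processed values is on a log2 scale; that it was shifted to the 75th percentile of each array, centred per probe on the median of the 12 arrays and averaged over spots was found from the values and is not stated by the authors. Its column medians ran from -0.170 to 0.0577, and it differed from the scanner values treated the same way by at most 0.00908 log2 on any array. It is therefore no independent processing of these arrays. Of its 6316 probes, 60 were no gene probe.

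The values analysed are log2 of the processed spot intensity, averaged over the unmarked spots of a probe and reduced by the 75th percentile of the gene probes of that array. Each of the 6256 gene probes had 7 spots, 43792 gene spots on an array. A probe counted as detected where more than 50% of its spots were well above background, a threshold chosen after the data were seen. A gene was kept where it was detected on both arrays of at least 1 group. This left 6083 genes, with 173 left out as dim, and 5798 of them were detected on all 12 arrays. No gene had several probes. Names come from the RefSeq gene table of the reference strain; 5756 probes matched a locus of it and 500 did not, 403 of these among the kept genes, which keep the name on the array. A probe can share signal between near-identical genes, such as ADH1 with ADH2, ADH3 and ADH5, paired ribosomal protein genes, and MAL12 with MAL32.

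The arrays lay on 3 slides of 4 arrays, each slide holding 2 groups. The control strain at 0 mM shared a slide with TAL-ADH at 70 mM, TAL at 0 mM with TAL-ADH at 0 mM, and the control strain at 70 mM with TAL at 70 mM. Only 2 comparisons, TAL minus control at 70 mM and TAL-ADH minus TAL at 0 mM, lie within a slide. In every other comparison of single groups the slide and the groups cannot be told apart, and a slide term could not be fitted beside the 6 group means. In the furfural effect over the 3 strains a slide term could be fitted, and its result stands beside that comparison. The scan dates divide the arrays exactly as the slides do.

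Each gene was fitted with limma 3.58.1 in R 4.3.3 (with the packages data.table, version 1.17.8, and jsonlite, version 2.0.0) on the 6 group means with 6 residual degrees of freedom, and the spread was moderated across genes (prior SD 0.294 log2, 3.11 prior degrees of freedom, median residual SD 0.316). The 13 comparisons are furfural against none in each strain and over the 3 strains (additive in strain and furfural, 8 residual degrees of freedom), the 3 pairs of strains at each dose, and the 3 differences between strains in the furfural effect. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 6083 genes. The adjusted p of a gene also depends on how many other genes differ in that comparison. A change of equal or larger size can therefore pass in 1 comparison and not in another. Changes are log2 with the standard error of the fit (SE) and 2 arrays per group. Against a group in which a gene was not detected, a fold is given only as a lower bound.

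The 29 gene lists were fixed before the data were examined. They are the pentose phosphate pathway without TAL1, glycolysis with pyruvate decarboxylase, alcohol dehydrogenases without ADH1, aldehyde reductases and related oxidoreductases, aldehyde dehydrogenases, oxidative stress, heat shock proteins and chaperones, trehalose and glycogen metabolism, pleiotropic drug resistance, cytosolic ribosomal proteins and mitochondrial ribosomal proteins. They go on with ribosome biogenesis, the proteasome, the tricarboxylic acid cycle, oxidative phosphorylation, gluconeogenesis with the glyoxylate cycle, amino acid biosynthesis, sulfate assimilation with methionine, iron uptake, hexose transporters, glycerol metabolism and ergosterol biosynthesis. The rest are the unfolded protein response, core histones, cyclins with S-phase genes, fatty acid oxidation, thiamine and pyridoxine synthesis, and the a-specific and alpha-specific genes as markers of mating type. They list 743 names, of which 737 were measured, 1 had no probe and the others were not kept. Each list was tested against the other genes with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 29 lists of a comparison. Members were also adjusted over the list alone.

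The rule for named genes was also fixed before the data were examined. It takes TAL1, ADH1 and XKS1 in every comparison. In each furfural comparison it takes the 6 largest rises and 6 largest falls among called genes whose 70 mM arrays both lay beyond both 0 mM arrays. In each strain comparison it takes up to 5 largest rises and falls with arrays that do not overlap, and in each difference of furfural effects up to 5 of each. Not every gene so taken is named in the text, but all are in the counts and lists. From each list it takes up to 4 members called over the 3 strains and up to 3 called in a difference. Transposon and mitochondrial features stand outside the rule for largest changes. Other examples of list members, and URA3, LEU2, AI4, YDL118W and YDL151C, were chosen after their values were seen.

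The alternatives fixed beforehand were quantile normalization, normexp background correction, no filter on dim probes, detection on all 12 arrays, the deposited processed values, the run number as a replicate block, the slide as a block, only the arrays of the groups compared, a log2 change of at least 1, and leaving out each array in turn. Normexp had been meant for mean spot intensities, which the files do not hold, and used the median intensities of spot and background with an offset of 50. A fit without the arrays labelled TAL 0 mM and TAL-ADH 70 mM was added after the data were seen. A choice between probes of 1 gene had nothing to compare, and a block of scan date would repeat the slide. The fit was tested on simulated data with changes added, up or down, in the control strain's furfural comparison. In the same data set, 100 genes were changed by log2 1 and 100 others by log2 2. The fit recovered 29 of 100 at log2 1 and 71 of 100 at log2 2, all with the right sign. It called 5 unchanged genes, and made 0 calls by limma in the 7 comparisons left untouched. The shifted list was called and 0 of 20 random lists were. The simulated noise was drawn independently for each gene and array, with no correlation between genes and no slide or run structure. The test therefore cannot show how often a gene or list call on the real arrays is false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.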

Results

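Gene expression was measured in 12 samples of xylose-fermenting yeast, 2 runs for each of 3 strains after 6 h without furfural or with 70 mM furfural. The series description names furfural tolerance during ethanol production from xylose as its subject, so the comparisons ask how furfural changes expression in each strain and how the strains differ at each dose. Between 94.8% and 97.9% of the gene spots of an array were well above background, and 5914 to 6121 genes were detected on each. The 75th percentile of the processed signal ranged from 2535 to 7414 intensity units. Across genes, the 2 runs of a group correlated at r = 0.945 to 0.985; genes are not independent replicates. The number of arrays limits the precision, and the median SE of a comparison of groups was 0.309 log2.

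The arrays fell into 2 sets that cross the labels. On the main axis of variation, which held 61.5% of the variance, the arrays labelled control 70 mM, TAL 70 mM and TAL 0 mM lay between 31.6 and 54.9. Those labelled control 0 mM, TAL-ADH 0 mM and TAL-ADH 70 mM lay between -47.0 and -39.1. The mean profile of TAL at 0 mM correlated across genes at 0.969 with TAL at 70 mM and at 0.872 with the control strain at 0 mM. The mean profile of TAL-ADH at 70 mM correlated at 0.992 with the control strain at 0 mM and at 0.861 with the control strain at 70 mM. Every comparison that uses the arrays labelled TAL 0 mM or TAL-ADH 70 mM is reported by its label.

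TAL1, which encodes transaldolase of the pentose phosphate pathway, was lowest in the control strain, at a mean log2 level of 2.58 ± 0.33 (SD, n = 2) without furfural and 0.71 ± 0.24 with it. It stood at 3.71 ± 0.38 and 2.82 ± 0.07 in the TAL strain and at 3.81 ± 0.22 and 4.02 ± 0.62 in the TAL-ADH strain. ADH1, which encodes the main alcohol dehydrogenase of ethanol formation, stood at 6.30 ± 0.12 and 5.38 ± 0.38 in the control strain, 4.92 ± 0.37 and 4.54 ± 0.24 in TAL, and 5.69 ± 0.96 and 6.09 ± 0.16 in TAL-ADH. URA3, which encodes a pyrimidine synthesis enzyme and is a common plasmid marker, stood at 0.34 ± 0.43 in TAL at 70 mM and at 1.09 ± 0.14 in TAL-ADH at 70 mM. In the 4 other groups URA3 stood at 3.69 to 4.97, and it was chosen after its values were seen. XKS1, which encodes xylulokinase of xylose use, stood at 2.49 ± 0.11 in TAL and 2.69 ± 0.02 in TAL-ADH at 70 mM, and at 3.40 to 4.01 in the 4 other groups. Whether these levels differ is tested under each comparison.

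**Figure D1:**
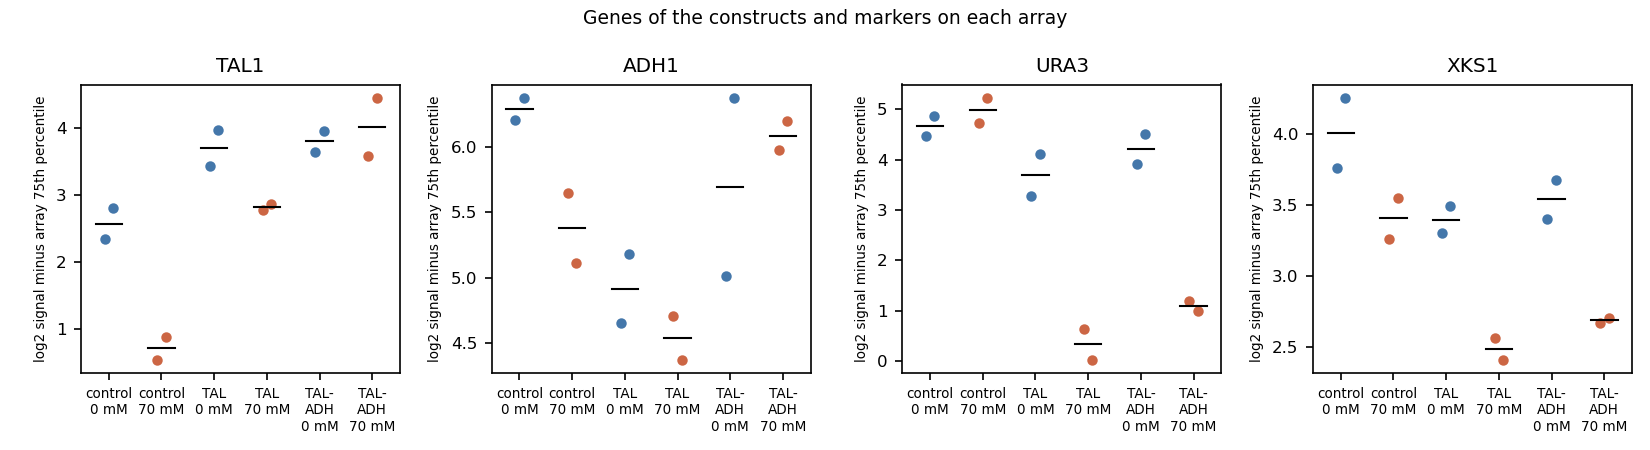
Log2 level of TAL1, ADH1, URA3 and XKS1 relative to the 75th percentile of each array (vertical axis) in the 6 groups of strain and furfural dose (horizontal axis), with a point for each array and a black line at the group mean. Mean TAL1 ranged from 0.71 in the control strain at 70 mM to 4.02 in the arrays labelled TAL-ADH 70 mM, and mean URA3 was 0.34 in TAL and 1.09 in TAL-ADH at 70 mM.

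In the control strain, furfural raised CIS1 429-fold (log2 8.74 ± 0.33 SE, n = 2 against 2), the nitroreductase gene FRM2 by log2 7.83 ± 0.27, and the open reading frames YKL070W by 6.76 ± 0.45 and YCL027C-A by 6.75 ± 0.22. OSI1 rose by 6.40 ± 0.45 and SPS100, a spore wall gene, by 6.31 ± 1.16. The largest falls were in ribosomal protein genes and lysine synthesis: RPL21A (-4.18 ± 0.43), LYS9 (-3.92 ± 0.58), RPL8A (-3.85 ± 0.48), RPS9B (-3.80 ± 0.45), RPS18B (-3.75 ± 0.28) and RPL27B (-3.67 ± 0.43). TAL1 fell by 1.86 ± 0.34 (adjusted p = 0.00323), while ADH1 (-0.92 ± 0.42, adjusted p = 0.116) and XKS1 (-0.60 ± 0.23, adjusted p = 0.0735) did not pass the test. By limma, 2156 of 6083 genes changed, 849 higher and 1307 lower, 1667 of them by at least 1 log2. The median change of all genes was -0.184, and -0.0641 after quantile normalization, under which ADH1 passed (-1.41, adjusted p = 0.00436) and XKS1 passed (adjusted p = 0.0113). The count was 1111 without control 0 mM run 1, 1186 without control 0 mM run 2 and 1341 without control 70 mM run 2. ADH1 passed without either TAL-ADH 0 mM array (adjusted p = 0.0326), and the 0 and 70 mM arrays lay on different slides.

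The gene lists of this and the next 2 paragraphs are for furfural in the control strain, and the examples in them, and those named beside a list further on, were chosen after their values were seen. They were not refitted under the alternatives, so a call of one was not tested with an array left out. Of 26 measured aldehyde reductases and related oxidoreductases, 16 rose, 2 fell and 8 did not pass (17 rose and 3 fell adjusted over the list alone), among them GRE2 (6.30 ± 0.34), a methylglyoxal reductase gene, and YLR460C (6.18 ± 0.49). The list passed at adjusted p = 1.09e-08 (median 1.88), but not with the correlation estimated (adjusted p = 0.232 with an estimated correlation). Of 9 alcohol dehydrogenases other than ADH1, 4 rose and 2 fell (4 and 3 adjusted over the list alone), with SFA1, a formaldehyde dehydrogenase gene, at 4.81 ± 0.31 and ADH2 at 3.24 ± 0.86. The alcohol dehydrogenase list did not pass (median 0.79, adjusted p = 0.105). ALD4 (4.59 ± 0.44) and ALD6 (4.53 ± 0.78) were the 2 of 5 aldehyde dehydrogenases that rose, the same 2 adjusted over the list alone, and 0 fell. The aldehyde dehydrogenase list had adjusted p = 0.023 (adjusted p = 0.232 with an estimated correlation), and 0.0745 without control 70 mM run 2. Of 29 oxidative stress genes 19 rose and 1 fell, the same numbers adjusted over the list alone, with SRX1, a sulfiredoxin gene, at 5.91 ± 0.47 and FLR1, a multidrug transporter gene, at 5.63 ± 0.21. The oxidative stress list had a median of 1.62 and adjusted p = 6.32e-09 (adjusted p = 0.232 with an estimated correlation). Of 15 pleiotropic drug resistance genes 9 rose and 0 fell, 9 adjusted over the list alone, with RSB1 at 5.89 ± 0.32 and the transporter gene SNQ2 at 5.47 ± 0.23. The drug resistance list had a median of 1.93 and adjusted p = 1.74e-05 (adjusted p = 0.232 with an estimated correlation). Of 28 heat shock proteins and chaperones 26 rose and 0 fell (27 adjusted over the list alone), with HSP30 at 4.42 ± 0.29 and HSP26 at 4.27 ± 0.59. The heat shock list had a median of 2.48 and adjusted p = 2.22e-14 (adjusted p = 0.232 with an estimated correlation). Sulfate assimilation and methionine genes rose in 18 of 23 and fell in 1, the same adjusted over the list alone, with MUP1, a methionine permease gene, at 4.78 ± 0.32 and STR3 at 4.35 ± 0.45. The sulfate and methionine list had a median of 2.23 and adjusted p = 4.48e-12 (adjusted p = 0.232 with an estimated correlation). Of 33 proteasome genes 11 rose and 0 fell (12 adjusted over the list alone), with RPN4, the regulator of the others, at 2.15 ± 0.25. The proteasome list had a median of 0.61 and adjusted p = 8.91e-05 (adjusted p = 0.626 with an estimated correlation).

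Of 138 cytosolic ribosomal protein genes 132 fell, 0 rose and 6 did not pass (134 fell adjusted over the list alone), with a list median of -2.78 (adjusted p = 6.34e-39; adjusted p = 0.232 with an estimated correlation). Of 39 ribosome biogenesis genes 6 fell and 0 rose (4 adjusted over the list alone), with CBF5 at -1.95 ± 0.44 and NOP58 at -1.78 ± 0.46. The ribosome biogenesis list had a median of -0.61 and adjusted p = 0.0237 (adjusted p = 0.81 with an estimated correlation). It was lost without control 0 mM run 1 (adjusted p = 0.0619) or control 70 mM run 2 (0.304). Of 20 genes of glycolysis and pyruvate decarboxylase 11 fell and 0 rose, 11 adjusted over the list alone, with TDH2 at -3.04 ± 0.35 and PGK1 at -2.63 ± 0.33. The glycolysis list had a median of -1.12 and adjusted p = 0.00608 (adjusted p = 0.464 with an estimated correlation). Of 21 cyclins and S-phase genes 12 fell and 0 rose, 12 adjusted over the list alone, with RNR1, a ribonucleotide reductase gene, at -2.91 ± 0.46 and CDC6 at -2.79 ± 0.25. The cyclin list had adjusted p = 0.000364 (adjusted p = 0.232 with an estimated correlation). Of 16 genes of gluconeogenesis and the glyoxylate cycle 11 rose and 0 fell (14 adjusted over the list alone), with PCK1 at 3.81 ± 0.54 and MLS1, a malate synthase gene, at 2.76 ± 0.38. The gluconeogenesis list had a median of 2.03 and adjusted p = 1.12e-07 (adjusted p = 0.232 with an estimated correlation). Of 15 genes of fatty acid oxidation 6 rose and 1 fell, the same adjusted over the list alone, with the catalase gene CTA1 at 4.02 ± 0.48 and POT1 at 2.40 ± 0.47. The fatty acid list had a median of 0.61 and adjusted p = 0.00442 (adjusted p = 0.232 with an estimated correlation). Of 20 hexose transporters and sensors 7 rose and 0 fell (8 adjusted over the list alone), with HXT5 at 3.42 ± 0.76 and HXT11 at least 4.72-fold higher. The hexose transporter list had a median of 0.74 and adjusted p = 0.00998 (adjusted p = 0.232 with an estimated correlation). Of 14 iron uptake genes 4 rose and 0 fell, 4 adjusted over the list alone, with FRE3 at 2.19 ± 0.31 and FIT1 at 1.70 ± 0.32. The iron uptake list had a median of 0.55 and adjusted p = 0.0237 (adjusted p = 0.464 with an estimated correlation). It too was lost without control 0 mM run 1 (adjusted p = 0.0619) or control 70 mM run 2 (0.154).

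The other lists did not pass in the control strain. Of 10 pentose phosphate genes besides TAL1, 2 rose, among them ZWF1 (1.69 ± 0.29), and 3 fell, among them TKL1 (-2.07 ± 0.35), the same adjusted over the list alone (adjusted p = 0.346). Of 20 trehalose and glycogen genes 5 rose, NTH2 by 3.75 ± 0.43, and 1 fell, the same adjusted over the list alone (adjusted p = 0.053). Of 50 amino acid biosynthesis genes 3 rose and 6 fell (1 and 5 adjusted over the list alone), with ILV5 at -3.45 ± 0.49 and LYS12 at -3.33 ± 0.31 (adjusted p = 0.346). Of 16 genes of the unfolded protein response 2 rose and 5 fell, the same adjusted over the list alone, with ERO1 at 3.13 ± 0.41 and SIL1 at -2.58 ± 0.22 (adjusted p = 0.244). Mitochondrial ribosomal protein genes rose in 2 and fell in 10 of 67 (0 and 1 adjusted over the list alone; adjusted p = 0.244). Oxidative phosphorylation genes rose in 3 and fell in 2 of 32 (0 adjusted over the list alone; adjusted p = 0.437). None of the 15 tricarboxylic acid cycle genes passed, over all genes or adjusted over the list alone (adjusted p = 0.244). Ergosterol genes rose in 1 and fell in 1 of 25 (0 adjusted over the list alone; adjusted p = 0.35). HTA2 fell alone among 11 core histone genes, also adjusted over the list alone (-1.43 ± 0.34, list adjusted p = 0.35). Thiamine and pyridoxine genes rose in 2 and fell in 2 of 20, the same adjusted over the list alone (adjusted p = 0.998). Glycerol genes rose in 2 and fell in 1 of 11, the same adjusted over the list alone (adjusted p = 0.573). The a-specific genes rose in 1 and fell in 1 of 5, the same adjusted over the list alone (adjusted p = 0.63). In both of these lists the median was negative and the test positive. Of 4 alpha-specific genes 2 rose, the pheromone gene MF(ALPHA)2 by 1.85 ± 0.39, and 1 fell, the same adjusted over the list alone (adjusted p = 0.428).

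**Figure D2:**
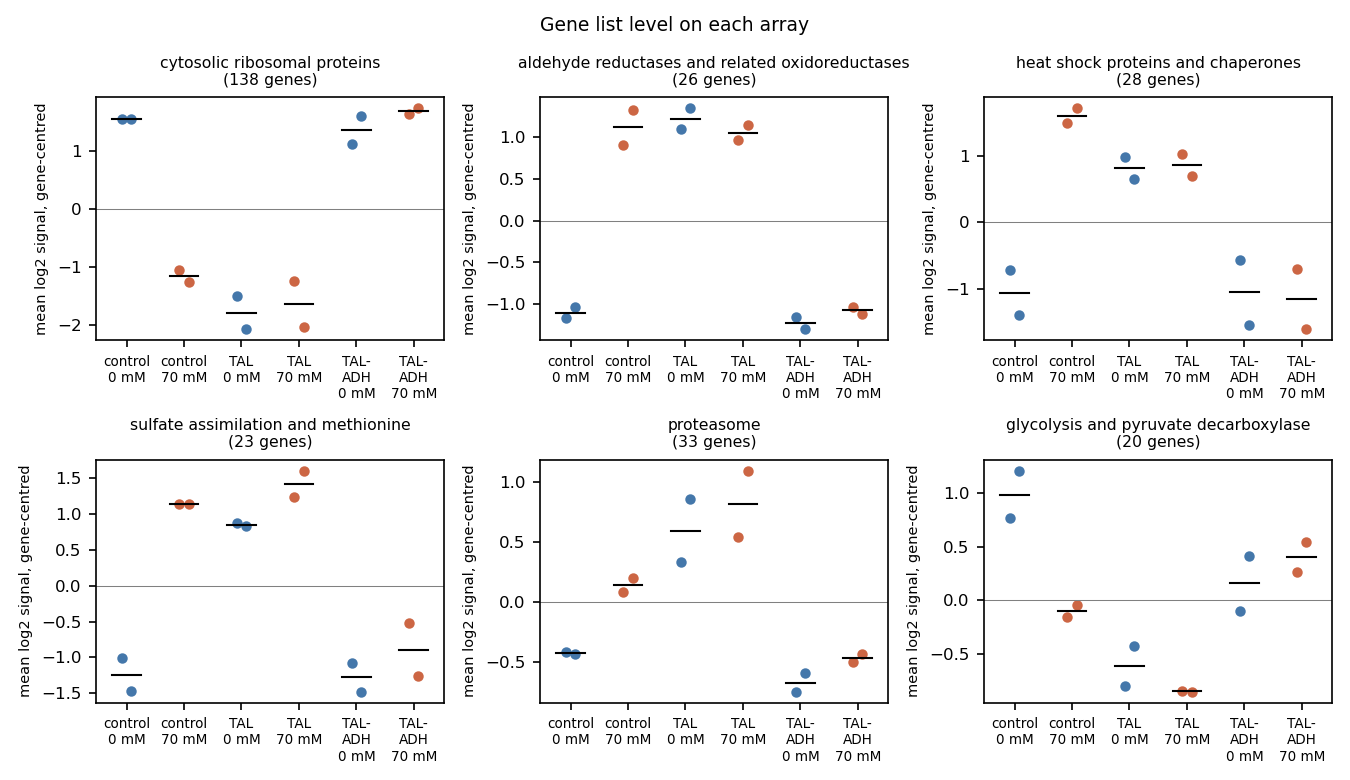
Mean level of the genes of 6 lists on each array (vertical axis, log2 centred per gene on the 12 arrays) in the 6 groups of strain and furfural dose (horizontal axis), with a point for each array and a black line at the group mean. Cytosolic ribosomal protein genes averaged 1.55, 1.36 and 1.69 in control 0 mM, TAL-ADH 0 mM and TAL-ADH 70 mM, and -1.16, -1.80 and -1.65 in control 70 mM, TAL 0 mM and TAL 70 mM.

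In the arrays labelled TAL, furfural raised the open reading frames YOL150C, at least 7.95-fold (n = 2 against 2, adjusted p = 0.0172), and YNL276C (log2 1.97 ± 0.25 SE, adjusted p = 0.0202). URA3 fell by 3.35 ± 0.36 (adjusted p = 0.0154) and AVL9 by 1.92 ± 0.21 (adjusted p = 0.0154). KRE29 was at least 2.69-fold lower (adjusted p = 0.0154), and AI4, encoded in an intron of a mitochondrial gene and outside the rule for largest changes, at least 1.85-fold lower (adjusted p = 0.00102). The 0 and 70 mM arrays lay on different slides. AI4 stood higher on every array of the slide of TAL 0 mM and TAL-ADH 0 mM than on all other arrays, so its call may come from the slide. TAL1 (-0.89 ± 0.34), ADH1 (-0.38 ± 0.42) and XKS1 (-0.91 ± 0.23) did not pass, with adjusted p = 0.28, 0.744 and 0.158. Sulfate and methionine genes were higher as a list (median 0.65, adjusted p = 1.32e-06), as were proteasome (0.17, 0.00234), oxidative phosphorylation (0.18, 0.00436) and oxidative stress genes (0.15, 0.0233). No member of these passed, 0 also adjusted over the list alone, and each list had adjusted p = 0.925 with an estimated correlation. Cytosolic ribosomal protein (median 0.17, adjusted p = 0.00234) and ergosterol genes (0.21, 0.0442) were also higher as lists, with 0 members adjusted over the list alone and adjusted p = 0.925 with an estimated correlation. Both turned direction in other fits. Without TAL 0 mM run 1 or TAL 70 mM run 2 the oxidative stress (adjusted p = 0.787 and 0.91) and proteasome lists (0.919 and 0.929) were lost. Without TAL 0 mM run 2 or TAL 70 mM run 1 the oxidative phosphorylation (0.0711 and 0.245), ribosomal protein (0.957 and 0.104) and ergosterol lists (0.794 and 0.759) were lost, the last also without either TAL-ADH 0 mM array (0.0572). Normexp ended all 5 of these (adjusted p = 0.0521 to 0.43), and quantile normalization all but the ribosomal protein list (0.32 to 0.491). By limma 6 genes changed, 2 higher and 4 lower, with 843 at unadjusted p under 0.05. Quantile normalization called 6 (4 higher, 2 lower) and normexp 1 (0 higher, 1 lower). Normexp moved the median of all genes from -0.0806 to 0.0633 and turned KRE29 to 0.57. The count was 1 without TAL 0 mM run 2 or either TAL 70 mM array, 2 without TAL 0 mM run 1, and 64 without either TAL-ADH 0 mM array. URA3 was lost without TAL 0 mM run 2 (adjusted p = 0.154), TAL 70 mM run 1 (0.0776) or run 2 (0.199). YOL150C and YNL276C were lost without any array of TAL or of control 0 mM (adjusted p = 0.0519 to 0.276), and AVL9 and KRE29 without any array of TAL (0.108 to 0.251). By limma 0 genes were called in the arrays of this strain alone, and 55 (11 higher, 44 lower) with the run number as a block.

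In the arrays labelled TAL-ADH, URA3 (log2 -3.12 ± 0.36 SE, n = 2 against 2, adjusted p = 0.0361) and AI4 (adjusted p = 0.0142) were lower at 70 mM, and no gene was called higher. The 0 and 70 mM arrays lay on different slides. AI4 was detected on 1 of 2 arrays at 0 mM and on neither at 70 mM, so no size is given. It stood higher on every array of the slide of TAL 0 mM and TAL-ADH 0 mM than on all other arrays, so its call may come from the slide. TAL1 (0.22 ± 0.34), ADH1 (0.39 ± 0.42) and XKS1 (-0.85 ± 0.23) did not pass, each with adjusted p = 0.999. GRE2 (0.35 ± 0.34) and SFA1 (0.15 ± 0.31), chosen after their values were seen, did not pass either. Cytosolic ribosomal protein genes were higher as a list (median 0.32, adjusted p = 2.12e-15), as were sulfate and methionine (0.33, 2.17e-05), proteasome (0.20, 0.000393) and glycolysis genes (0.27, 0.0073). None of these had a member past the test, 0 also adjusted over the list alone, and all had adjusted p = 0.925 with an estimated correlation. Hexose transporters (median 0.31, adjusted p = 0.0217; 1 member higher adjusted over the list alone; adjusted p = 0.566 with an estimated correlation) were also higher as a list. So were oxidative phosphorylation genes (0.10, 0.0485; 0 adjusted over the list alone; adjusted p = 0.925 with an estimated correlation), which turned direction in 1 other fit. Without TAL-ADH 0 mM run 1 the glycolysis (adjusted p = 0.812), ribosomal protein (0.282), proteasome (0.187), hexose transporter (0.282) and oxidative phosphorylation lists (0.386) were lost. Without TAL-ADH 70 mM run 2 the glycolysis and oxidative phosphorylation lists were lost (both 0.182), and the second also without any array of control or TAL (0.0533 to 0.063). The sulfate list was lost without TAL-ADH 0 mM run 2 (adjusted p = 0.111) or TAL-ADH 70 mM run 1 (0.669). Quantile normalization ended the glycolysis (0.652) and oxidative phosphorylation lists (0.704), and normexp the hexose transporter list (0.0587). By limma 2 genes changed, with 213 at unadjusted p under 0.05. The count was 46 without TAL-ADH 0 mM run 1, 0 without TAL-ADH 0 mM run 2, either TAL-ADH 70 mM or either control 0 mM array, and 1 without either TAL 70 mM or either control 70 mM array. Each array with a count of 0 or 1 also lost URA3, with adjusted p = 0.0556 to 0.595. Without TAL-ADH 70 mM run 2, 11 lists were called instead of 6. Quantile normalization called 1 gene and normexp 0.

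Over the 3 strains together, no single gene passed for furfural. XKS1 (log2 -0.78 ± 0.14 SE, n = 6 against 6, adjusted p by limma = 0.0799), TAL1 (-0.84 ± 0.32, 0.174), ADH1 (-0.30 ± 0.28, 0.513) and GRE2 (2.20 ± 0.89, 0.192) did not pass, GRE2 chosen after its values were seen. As lists, sulfate and methionine genes (median 1.08, adjusted p = 6.19e-14; 22 higher and 1 lower adjusted over the list alone) and proteasome genes (0.38, 9.1e-09; 3 higher and 0 lower adjusted over the list alone) were higher. So were heat shock genes (0.86, 4.94e-09; 0 adjusted over the list alone), and each of the 3 had adjusted p = 0.509 with an estimated correlation. Cytosolic ribosomal protein genes were lower (median -0.76, adjusted p = 8.17e-08; 0 adjusted over the list alone; adjusted p = 0.784 with an estimated correlation), and 14 lists were called in all. The ribosomal protein mean fell in the control strain alone, from 1.55 to -1.16, and went from -1.80 to -1.65 in TAL and 1.36 to 1.69 in TAL-ADH. The heat shock mean went from -1.06 to 1.60 in control, 0.81 to 0.86 in TAL and -1.05 to -1.16 in TAL-ADH. Sulfate and proteasome means were higher at 70 mM in each strain. By limma 0 genes were called, with 1381 at unadjusted p under 0.05 and a smallest adjusted p of 0.0756. A slide block left no freedom between groups, so its furfural term was the effect in the control strain minus that in TAL plus that in TAL-ADH, not an effect over the 3 strains. That term called 216 genes, 128 higher and 88 lower, and 15 lists. Without TAL-ADH 0 mM run 2 the count was 432 and XKS1 passed (adjusted p = 0.0251), and without control 70 mM run 1 it was 1.

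In the arrays labelled TAL 0 mM, YKL070W (log2 7.52 ± 0.45 SE, n = 2 against 2), FRM2 (6.90 ± 0.27), OSI1 (6.36 ± 0.45), CIS1 (6.27 ± 0.33) and GRE2 (6.14 ± 0.34) were highest above the control strain at 0 mM. RPL43B (-4.78 ± 0.53), LYS9 (-4.75 ± 0.58), RPL8A (-4.70 ± 0.48) and RPP2A (-4.58 ± 0.52) were among those furthest below it. TAL1 was higher by 1.14 ± 0.34 (adjusted p = 0.0332), ADH1 was lower (-1.38 ± 0.42, adjusted p = 0.0356) and XKS1 did not pass (-0.61 ± 0.23, 0.0825). Of 138 cytosolic ribosomal protein genes 134 were lower and 0 higher (136 adjusted over the list alone), with a median of -3.43 (adjusted p = 9.36e-65; adjusted p = 0.281 with an estimated correlation). Of 33 proteasome genes 22 were higher (30 adjusted over the list alone), PRE7 by 1.63 ± 0.27 (median 0.96, adjusted p = 4.24e-09; adjusted p = 0.458 with an estimated correlation). Of 32 oxidative phosphorylation genes 21 were lower (22 adjusted over the list alone), COX8 by -1.52 ± 0.30 (median -1.04, adjusted p = 4.48e-08; adjusted p = 0.285 with an estimated correlation). Glycolysis genes were lower in 16 and higher in 1 of 20, the same adjusted over the list alone, HXK2 by -2.86 ± 0.57 (adjusted p = 4.05e-07; adjusted p = 0.285 with an estimated correlation). By limma 1728 genes differed, 909 higher and 819 lower, and the 2 groups lay on different slides. The count was 759 without control 0 mM run 1, 838 without control 0 mM run 2 and 924 without TAL 0 mM run 2. TAL1 was lost without any of these 3 arrays (adjusted p = 0.201, 0.0642 and 0.187). ADH1 was lost without any array of the control 0 mM, TAL 0 mM or TAL-ADH 70 mM groups (adjusted p = 0.0531 to 0.155), and with quantile normalization (-0.70, adjusted p = 0.075).

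At 0 mM, TAL-ADH and the control strain differed in AI4 alone (higher in TAL-ADH, n = 2 against 2, adjusted p = 0.0224). It was detected on neither control array and on 1 of 2 TAL-ADH arrays, so no size is given, and was chosen after its values were seen. AI4 stood higher on every array of the slide of TAL 0 mM and TAL-ADH 0 mM than on all other arrays, so its call may come from the slide. TAL1 (log2 1.23 ± 0.34 SE, adjusted p = 0.394), ADH1 (-0.60 ± 0.42, 0.855) and XKS1 (-0.47 ± 0.23, 0.777) did not pass. The TAL1 change was no smaller than the one called in TAL minus control at 0 mM, where 1728 genes were called. Glycolysis genes were lower as a list (median -0.87, adjusted p = 1.26e-12; 0 passed over all genes and 10 were lower adjusted over the list alone; adjusted p = 0.515 with an estimated correlation). Mitochondrial ribosomal protein genes were higher as a list (median 0.41, adjusted p = 2.52e-12; 0 passed adjusted over the list alone; adjusted p = 0.813 with an estimated correlation), and 7 lists were called in all. Cytosolic ribosomal protein genes were lower (median -0.19, adjusted p = 5.15e-05; 0 passed adjusted over the list alone; adjusted p = 0.953 with an estimated correlation), a direction that turned in 1 other fit. Without TAL-ADH 0 mM run 1 (adjusted p = 0.795) or with quantile normalization (0.9) this list was lost, and the mitochondrial one without TAL-ADH 0 mM run 2 (0.139). By limma 1 gene was called, with 429 at unadjusted p under 0.05, and the groups lay on different slides. Without TAL-ADH 0 mM run 1 there were 62 genes and 4 lists, and without any other single array 0 genes, as with quantile normalization, normexp, or the fit without the arrays labelled TAL 0 mM and TAL-ADH 70 mM.

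At 0 mM, TAL-ADH and TAL shared a slide. Ribosomal protein genes were among the highest in TAL-ADH relative to TAL, with RPL21A (log2 4.84 ± 0.43 SE, n = 2 against 2), RPL43B (4.64 ± 0.53), RPS11A (4.39 ± 0.41) and RPS8B (4.35 ± 0.30). YKL070W (-7.08 ± 0.45), FRM2 (-6.81 ± 0.27), OSI1 (-6.65 ± 0.45), GRE2 (-6.07 ± 0.34) and CIS1 (-5.76 ± 0.33) were lowest. TAL1 (0.10 ± 0.34, adjusted p = 0.868), ADH1 (0.78 ± 0.42, 0.201) and XKS1 (0.14 ± 0.23, 0.7) did not pass, though ADH1 passed without TAL-ADH 0 mM run 1 (1.46, adjusted p = 0.0172). Cytosolic ribosomal protein genes were higher in 134 and lower in 1 of 138 (136 and 1 adjusted over the list alone; median 3.25, adjusted p = 9.15e-61; adjusted p = 0.259 with an estimated correlation). Proteasome genes were lower in 27 of 33 and higher in 0 (33 adjusted over the list alone; median -1.25, adjusted p = 2.74e-13; adjusted p = 0.406 with an estimated correlation). Sulfate and methionine genes were lower in 21 of 23 and higher in 0 (22 adjusted over the list alone), SUL2, a sulfate permease gene, by -3.52 ± 0.34 (list adjusted p = 2.02e-12; adjusted p = 0.302 with an estimated correlation). Pheromone gene MF(ALPHA)2 (-3.08 ± 0.39) and SAG1 (-1.23 ± 0.32) were the 2 of 4 alpha-specific genes that were lower, also adjusted over the list alone (list adjusted p = 0.0387; adjusted p = 0.506 with an estimated correlation). This list was lost without TAL 0 mM run 2 (adjusted p = 0.169) or TAL-ADH 0 mM run 1 (0.107), with quantile normalization (0.0624) and with normexp (0.145). By limma 1566 genes differed, 773 higher and 793 lower. The count was 723 without TAL 0 mM run 2, 807 without TAL-ADH 0 mM run 2, and 651 in a fit of the arrays of these 2 groups alone.

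At 70 mM, TAL and the control strain shared a slide and differed in 5 genes. YBR292C (log2 2.22 ± 0.24 SE, n = 2 against 2, adjusted p = 0.0215) and EFM6 (1.84 ± 0.21, 0.0235) were higher in TAL. URA3 (-4.64 ± 0.36, 0.00254), CIT3, a citrate synthase gene (-2.69 ± 0.33, 0.0249), and GPP1, a glycerol phosphatase gene (-2.65 ± 0.36, 0.0496), were lower. TAL1 did not pass (2.11 ± 0.34, 0.0628), nor did ADH1 (-0.84 ± 0.42, 0.354) or XKS1 (-0.91 ± 0.23, 0.139). This TAL1 change was larger than the one called in TAL minus control at 0 mM, where 1728 genes were called. The adjustment is stricter where few genes differ. TAL1 passed with quantile normalization (2.36, adjusted p = 0.0224) and with the run number as a block. It had adjusted p = 0.558 with only the arrays of the groups compared. Proteasome genes were higher as a list (median 0.64, adjusted p = 1.3e-10; 0 passed over all genes and 8 were higher adjusted over the list alone; adjusted p = 0.549 with an estimated correlation). Oxidative phosphorylation genes were lower (median -0.68, adjusted p = 1.64e-14; 0 passed over all genes and 16 were lower adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). Gluconeogenesis genes were lower (median -1.13, adjusted p = 1.71e-08; 0 passed over all genes and 8 were lower adjusted over the list alone; adjusted p = 0.352 with an estimated correlation). Glycolysis genes were also lower (median -0.80, adjusted p = 3.2e-08; 0 passed over all genes and 9 were lower and 1 higher adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). By limma 5 genes differed, 2 higher and 3 lower, with 984 at unadjusted p under 0.05. Quantile normalization called 12 (8 higher, 4 lower), and normexp, which moved the median of all genes from 0.0199 to 0.171, called 2 (0 higher, 2 lower). The arrays of the 2 groups alone gave 0 by limma. With the run number as a block, 357 genes were called (213 higher, 144 lower), but the labels do not show that a run pairs samples. The count was 44 without control 70 mM run 1, 0 without control 70 mM run 2, 1 without any array of TAL or of control 0 mM, and 2 without any TAL-ADH array. URA3 was lost without control 70 mM run 2 (adjusted p = 0.055) and no other single array. EFM6, CIT3 and GPP1 were lost without any array but control 70 mM run 1 (adjusted p = 0.0571 to 0.408), and YBR292C without the same arrays except those of TAL-ADH (0.0586 to 0.253).

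In the arrays labelled TAL-ADH 70 mM, against the control strain at 70 mM, RPL21A (log2 4.44 ± 0.43 SE, n = 2 against 2), the near-identical maltase genes MAL32 (4.14 ± 0.42) and MAL12 (4.13 ± 0.41), RPS9B (4.09 ± 0.45) and SOR2 (3.95 ± 1.02) were highest. CIS1 (-8.11 ± 0.33), FRM2 (-7.57 ± 0.27), YCL027C-A (-6.55 ± 0.22), YKL070W (-6.49 ± 0.45) and SPS100 (-6.46 ± 1.16) were lowest. TAL1 was higher by 3.31 ± 0.34 (adjusted p = 0.000172) and XKS1 lower (-0.71 ± 0.23, 0.0408), while ADH1 did not pass (0.71 ± 0.42, 0.21). Of 138 cytosolic ribosomal protein genes 132 were higher and 0 lower (134 adjusted over the list alone; median 2.98, adjusted p = 3.87e-39; adjusted p = 0.3 with an estimated correlation). Of 28 heat shock genes 26 were lower and 0 higher (27 adjusted over the list alone), HSP30 by -5.31 ± 0.29 (median -2.74, adjusted p = 1.04e-14; adjusted p = 0.3 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes 33 were higher and 0 lower (34 adjusted over the list alone), MRPL32 by 2.10 ± 0.33 (median 0.83, adjusted p = 6.44e-06; adjusted p = 0.577 with an estimated correlation). By limma 2226 genes differed, 1370 higher and 856 lower, on different slides. The median of all genes was 0.204, and 0.0488 after quantile normalization, which ended the call of XKS1 (adjusted p = 0.366) and gave one of ADH1 (1.33, adjusted p = 0.00554). The count was 1136 without TAL-ADH 70 mM run 2, 1297 without control 70 mM run 2 and 1310 without TAL-ADH 70 mM run 1. SOR2 was lost without control 70 mM run 2 (adjusted p = 0.0682) or TAL-ADH 70 mM run 2 (0.112). XKS1 was lost without control 70 mM run 2 (adjusted p = 0.178) or any array of TAL 0 mM (0.0523), TAL 70 mM (0.0555) or TAL-ADH 70 mM (0.15 and 0.141).

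At 70 mM, TAL-ADH against TAL gave RPL21A (log2 5.08 ± 0.43 SE, n = 2 against 2), RPL8A (4.81 ± 0.48), RPS9B (4.62 ± 0.45), RPS26B (4.47 ± 0.53) and RPS8B (4.43 ± 0.30) as the genes furthest up. YKL070W (-7.20 ± 0.45), FRM2 (-6.88 ± 0.27), CIS1 (-6.32 ± 0.33), OSI1 (-6.23 ± 0.45) and YDR278C (-6.01 ± 0.22) were furthest down. ADH1 was higher by 1.55 ± 0.42 (adjusted p = 0.0205) and TAL1 by 1.20 ± 0.34 (0.0245), and XKS1 did not pass (0.20 ± 0.23, 0.54). Of 138 cytosolic ribosomal protein genes 135 were higher and 0 lower, 135 adjusted over the list alone (median 3.43, adjusted p = 3.08e-52; adjusted p = 0.294 with an estimated correlation). Of 33 proteasome genes 30 were lower and 0 higher (33 adjusted over the list alone), RPN10 by -1.84 ± 0.29 (median -1.26, adjusted p = 2.62e-13; adjusted p = 0.405 with an estimated correlation). Of 20 glycolysis genes 14 were higher and 1 lower (16 and 1 adjusted over the list alone), TDH2 by 3.05 ± 0.35 (median 1.52, adjusted p = 0.00024; adjusted p = 0.467 with an estimated correlation). By limma 1940 genes differed, 1092 higher and 848 lower, on different slides. The median of all genes moved from 0.101 to -0.0421 with normexp, under which more genes were lower (812) than higher (722). The count was 951 without TAL-ADH 70 mM run 2, 964 without TAL 70 mM run 2 and 1146 without TAL-ADH 70 mM run 1. ADH1 was lost without TAL 70 mM run 2, at log2 1.38 (adjusted p = 0.115), or TAL-ADH 70 mM run 1 (0.0666) or run 2 (0.111). TAL1 was lost without TAL-ADH 70 mM run 2, at 0.76 (adjusted p = 0.184), or TAL 70 mM run 1 (0.0879) or run 2 (0.0907).

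**Figure D3:**
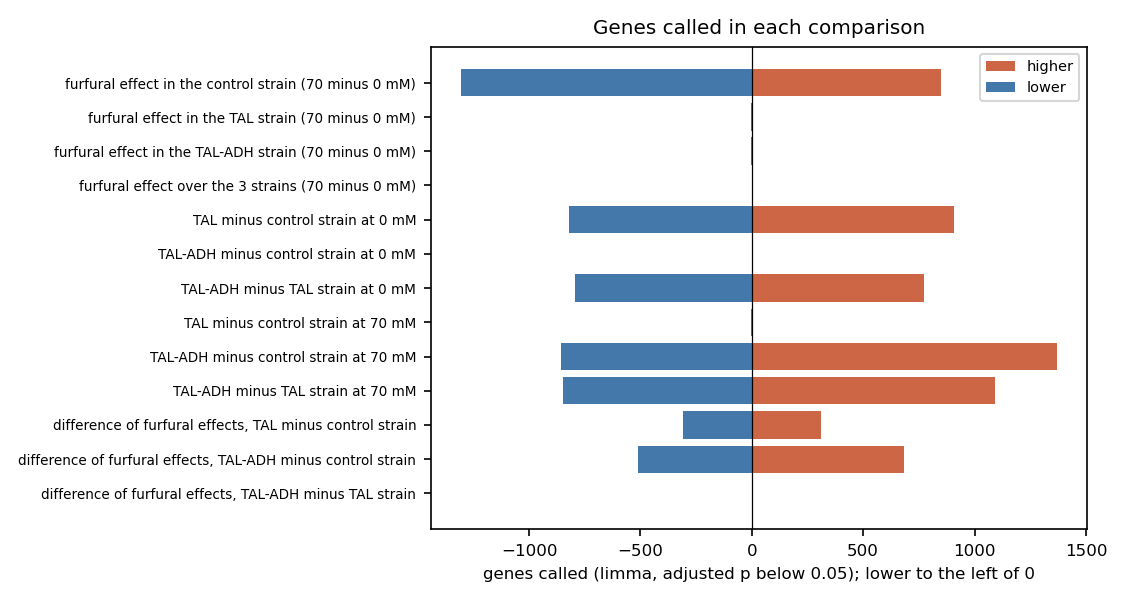
Number of genes called by limma in each of the 13 comparisons (vertical axis), with bars to the right for higher and to the left for lower genes (horizontal axis, number of genes). Furfural in the control strain called 849 higher and 1307 lower genes, and furfural in TAL 2 and 4.

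The furfural effect of TAL differed from that of the control strain most in CIS1 (difference in log2 -8.05 ± 0.47 SE, n = 2 in each of 4 groups), FRM2 (-7.58 ± 0.38), YKL070W (-6.82 ± 0.64), YCR102C (-6.57 ± 0.71) and YLR460C (-6.49 ± 0.69). All 5 were lower in TAL. Among the genes in which it was higher in TAL were LYS9 (4.03 ± 0.83), RPS26B (4.01 ± 0.76), RPL31A (3.99 ± 0.72) and RPP2A (3.95 ± 0.73). TAL1 (0.98 ± 0.47, adjusted p = 0.234), ADH1 (0.54 ± 0.59, 0.604) and XKS1 (-0.30 ± 0.33, 0.602) did not pass, and URA3, chosen after its values were seen, was lower (-3.67 ± 0.52, 0.00329). Of 138 cytosolic ribosomal protein genes 125 were higher and 0 lower (129 adjusted over the list alone; median 2.98, adjusted p = 9.84e-60; adjusted p = 0.186 with an estimated correlation). Of 28 heat shock genes 14 were lower and 0 higher (25 adjusted over the list alone), HSP30 by -4.27 ± 0.42 (adjusted p = 3.08e-14; adjusted p = 0.186 with an estimated correlation). Of 26 aldehyde reductases 15 were lower and 0 higher (16 and 1 adjusted over the list alone), OSI1 by -6.48 ± 0.64 (adjusted p = 3.56e-10; adjusted p = 0.186 with an estimated correlation). By limma 622 genes differed, 312 higher and 310 lower. The median moved from 0.0791 to 0.237 with normexp. The count was 282 without control 0 mM run 1, 310 without TAL 70 mM run 1, 360 without control 0 mM run 2, 398 without TAL 0 mM run 2 and 400 without control 70 mM run 2. LYS9 was lost without control 0 mM run 1 (adjusted p = 0.0673), TAL 70 mM run 1 (0.0635), control 70 mM run 2 (0.0592) or TAL 0 mM run 2 (0.055).

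The furfural effect of TAL-ADH differed from that of the control strain most in CIS1 (difference in log2 -8.61 ± 0.47 SE, n = 2 in each of 4 groups), FRM2 (-7.66 ± 0.38), SIP18 (-7.24 ± 1.25), SPS100 (-6.97 ± 1.64) and YKL070W (-6.93 ± 0.64). All 5 were lower in TAL-ADH. It was higher for RPL8A (4.75 ± 0.68), LYS9 (4.63 ± 0.83), ILV5 (4.39 ± 0.70), RPS0B (4.36 ± 0.39) and RPS26B (4.33 ± 0.76). TAL1 was higher by 2.08 ± 0.47 (adjusted p = 0.0165), URA3 lower (-3.44 ± 0.52, 0.00299), and ADH1 (1.31 ± 0.59, 0.149) and XKS1 (-0.24 ± 0.33, 0.633) did not pass. Of 138 cytosolic ribosomal protein genes 126 were higher and 0 lower (135 adjusted over the list alone; median 3.18, adjusted p = 4.35e-46; adjusted p = 0.349 with an estimated correlation). Of 28 heat shock genes 19 were lower and 0 higher (25 adjusted over the list alone; adjusted p = 4.15e-13; adjusted p = 0.349 with an estimated correlation). Of 20 glycolysis genes 10 were higher and 0 lower (11 adjusted over the list alone), PGK1 by 3.24 ± 0.47 (adjusted p = 0.00106; adjusted p = 0.384 with an estimated correlation). By limma 1194 genes differed, 683 higher and 511 lower. The count was 513 without TAL-ADH 70 mM run 2, 562 without control 0 mM run 1, 634 without control 0 mM run 2, 727 without TAL-ADH 70 mM run 1 and 791 without control 70 mM run 2. SPS100 was lost without control 0 mM run 1 (adjusted p = 0.0728), control 70 mM run 2 (0.0645), TAL-ADH 70 mM run 1 (0.0642) or TAL-ADH 0 mM run 2 (0.0594).

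Between TAL-ADH and TAL, the furfural effect differed in no gene by limma, with 406 at unadjusted p under 0.05 and a smallest adjusted p of 0.232. The differences were 1.102 ± 0.47 log2 in TAL1 (SE, n = 2 in each of 4 groups, adjusted p = 0.737), 0.77 ± 0.59 in ADH1 (0.934), 0.06 ± 0.33 in XKS1 (0.991) and 0.23 ± 0.52 in URA3 (0.991). No list was called. The median of all genes moved from 0.0659 to -0.0804 with normexp, which called 2 lists. Without TAL-ADH 0 mM run 1 there were 58 genes and 2 lists. The lists called were 7 without TAL-ADH 0 mM run 2, 6 without TAL 70 mM run 1, 5 without TAL 70 mM run 2, 4 without either TAL 0 mM array or TAL-ADH 70 mM run 1, and 3 without TAL-ADH 70 mM run 2.

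The furfural effects of the 3 strains, which share no array but do share slides, had 4 genes called the same way in the control strain and TAL. Independent lists would share 0.279 higher and 0.859 lower genes, against 2 and 2 observed; across genes the 2 effects correlated at r = 0.327 (rho = 0.356). The control strain and TAL-ADH shared 0 genes (r = -0.214), and TAL and TAL-ADH shared URA3 and AI4, against 0.0013 by independence (r = 0.203). Control and TAL shared a slide at 70 mM, TAL and TAL-ADH at 0 mM, and control 0 mM lay with TAL-ADH 70 mM. A slide effect alone would push the first 2 of these correlations up and that of control and TAL-ADH down. The numbers by independence take no account of the slides, so this sharing cannot be told from a slide effect. The control strain's furfural effect was also compared with TAL minus TAL-ADH at 0 mM, which lies on 1 slide and was chosen after its result was seen. These had 979 genes called the same way and 18 the opposite way, 445 higher against 111 by independence and 534 lower against 166 (r = 0.709). Genes are not independent replicates, so these correlations describe the effects and test nothing. The 4 shared genes of control and TAL became 49 without either TAL-ADH 0 mM array, 2 without control 0 mM run 1, and 0 without control 0 mM run 2 or any TAL array. The 0 of control and TAL-ADH became 1 and the 2 of TAL and TAL-ADH became 7 without TAL-ADH 0 mM run 1. The 2 became 0 without TAL-ADH 0 mM run 2 or any TAL-ADH 70 mM or control 0 mM array, and 1 without any control 70 mM or TAL 70 mM array or TAL 0 mM run 2.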

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

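Of the tests in this part, the one on an exchange of labels was written before its result was seen, and those on the slide and on the genes used for the exchange were chosen after. The furfural effect differed between TAL and the control strain in 622 genes and between TAL-ADH and the control strain in 1194. In TAL the effect was higher than in the control strain for LYS9 (difference in log2 4.03), RPS26B (4.01), RPL31A (3.99) and RPP2A (3.95). It was lower for YLR460C (-6.49), YCR102C (-6.57), YKL070W (-6.82), FRM2 (-7.58) and CIS1 (-8.05). In TAL-ADH the effect was higher for RPL8A (4.75), LYS9 (4.63), ILV5 (4.39), RPS0B (4.36) and RPS26B (4.33). It was lower for YKL070W (-6.93), SPS100 (-6.97), SIP18 (-7.24), FRM2 (-7.66) and CIS1 (-8.61).

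For the genes just named, these differences went with 2 groups, and how many of the other called genes did so was not counted. URA3, called in the difference of TAL and control, was an exception. It stood at 3.69 in TAL 0 mM and 0.34 in TAL 70 mM, against 4.66 and 4.97 in the control strain. The arrays labelled TAL 0 mM resembled the profile of furfural in the control strain, and those labelled TAL-ADH 70 mM lacked it. The likeness was partial, since TAL 0 mM and control 70 mM, on different slides, differed in 947 genes by limma. For the profile in TAL 0 mM the slide may be the cause, but it cannot be the whole of it. TAL and TAL-ADH at 0 mM lay on 1 slide. Their difference shared 979 genes with the furfural effect of the control strain, against 277 for independent lists. The absence of the profile in TAL-ADH 70 mM has no such comparison, because those arrays shared a slide with control 0 mM. For that absence the slide was not excluded as the whole cause. A second candidate explanation is that the labels of the 2 groups were exchanged, since an exchange would give all 3 strains the profile at 70 mM and none at 0 mM. Read from 95 genes that separate TAL from control at 70 mM, the TAL-ADH 70 mM arrays carried more of the TAL state in 8 (8.42%, 95% interval 3.71 to 15.9%), the side against an exchange by the bound written before. This interval and that of the premise below count genes as independent trials, which genes on the same arrays are not. They measure no spread between samples. The 2 groups set against each other also lay on different slides.

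The premise of that test was that its genes mark the TAL strain at either dose, and this was examined only after the result. The TAL-ADH 0 mM arrays lay nearer TAL 70 mM than control 70 mM in 23 of the 95 genes (24.2%, 95% interval 16.0 to 34.1%), so the genes may follow furfural in the TAL strains and the test leaves an exchange open. URA3 was low in the arrays labelled TAL 70 mM and TAL-ADH 70 mM alone, which would be a mark of the TAL strain under an exchange and an effect of furfural in both strains under the labels as given. URA3 was seen beforehand and tests neither. XKS1 was also lowest in these 2 groups (2.49 and 2.69, against 3.40 to 4.01), but its furfural effect was called in neither strain. Another candidate explanation is biological, that TAL expression alone brings on the stress profile without furfural and that ADH expression with TAL prevents it at 70 mM. It was not tested, and no array was regrouped.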

How the results depend on the processing

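The fit without the arrays labelled TAL 0 mM and TAL-ADH 70 mM was chosen after seeing the data, and the other alternatives before; the cause of each move was not tested. With normexp background correction the furfural effect called 1 gene in TAL and 0 in TAL-ADH, TAL-ADH minus control at 0 mM 0 genes and TAL minus control at 70 mM 2. The lists called were then 1 for furfural in TAL and 2 for the difference of effects of TAL-ADH and TAL, KRE29 turned to 0.57 in TAL, and 0 genes were shared by control and TAL and 0 by TAL and TAL-ADH. With quantile normalization furfural called 1 gene in TAL-ADH, TAL-ADH minus control at 0 mM 0 and TAL minus control at 70 mM 12; the lists called were 2 for furfural in TAL and 4 for TAL-ADH minus control at 0 mM, and TAL and TAL-ADH shared 1 gene. Under it TAL1 was 2.36 in TAL minus control at 70 mM, and ADH1 was -1.41 for furfural in the control strain, -0.70 in TAL minus control at 0 mM and 1.33 in TAL-ADH minus control at 70 mM. With genes well above background on all 12 arrays, furfural called 3 genes in TAL and 0 in TAL-ADH, TAL-ADH minus control at 0 mM 0, and the shared genes were 2 for control and TAL and 0 for TAL and TAL-ADH. With only the arrays of the groups compared, furfural called 0 genes in TAL and 0 in TAL-ADH, TAL-ADH minus control at 0 mM 0, TAL-ADH minus TAL at 0 mM 651 and TAL minus control at 70 mM 0, and 0 genes were shared by control and TAL and 0 by TAL and TAL-ADH. Without the arrays labelled TAL 0 mM and TAL-ADH 70 mM, TAL-ADH minus control at 0 mM called 0 genes and TAL minus control at 70 mM 1. With the slide as a block, the furfural term, which is then the effect in control minus that in TAL plus that in TAL-ADH, called 216 genes. With the correlation within lists estimated, 0 lists were called in each of the 12 comparisons that had any.

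The samples of a run share only a number in the labels. Run deviations correlated across genes over the 15 pairs of groups at 0.0435 to 0.861 (median 0.429), and 14 pairs exceeded 0.1, a hint from the data and not the design. Outside their group, 12 of 12 arrays correlated best with their own run. That follows from these positive correlations, because the deviations of the 2 runs of a group mirror each other, and it adds no evidence. With the run number as a block, furfural called 55 genes in TAL, TAL minus control at 0 mM 2608, TAL-ADH minus TAL at 0 mM 2499, TAL minus control at 70 mM 357, and the differences of effects from control 1351 for TAL and 2210 for TAL-ADH. TAL1 in TAL minus control at 70 mM was 2.11 with adjusted p = 0.00551, in a range of 0.00551 to 0.558 over its alternatives, and control and TAL shared 36 genes.

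With 1 array left out, the lone array of its group was taken to vary like the other groups. Furfural called 1111 to 2267 genes in the control strain, 1 to 64 in TAL, 0 to 46 in TAL-ADH and 0 to 432 over the 3 strains. At 0 mM the calls were 759 to 1857 for TAL minus control, 0 to 62 for TAL-ADH minus control and 723 to 1626 for TAL-ADH minus TAL. At 70 mM they were 0 to 44, 1136 to 2321 and 951 to 2052. The differences of effects called 282 to 792 genes for TAL and control, 513 to 1350 for TAL-ADH and control and 0 to 58 for TAL-ADH and TAL. In the same order the lists called were 12 to 17, 5 to 6, 5 to 11 and 12 to 15 for furfural, 13 to 16, 4 to 9 and 13 to 17 at 0 mM, 11 to 15, 11 to 16 and 13 to 16 at 70 mM, and 12 to 20, 9 to 15 and 0 to 7 for the differences. TAL1 ranged over -2.10 to -1.63, -1.16 to -0.62 and -0.22 to 0.66 for furfural in control, TAL and TAL-ADH, over 0.87 to 1.41, 1.00 to 1.47 and -0.18 to 0.37 at 0 mM, and over 1.94 to 2.29, 2.87 to 3.75 and 0.76 to 1.64 at 70 mM. ADH1 ranged over -1.18 to -0.65, -0.64 to -0.11 and -0.29 to 1.08 for furfural, over -1.65 to -1.12, -1.29 to 0.08 and 0.10 to 1.46 at 0 mM, and over -1.11 to -0.58, 0.44 to 0.97 and 1.38 to 1.72 at 70 mM. The shared genes were 0 to 49 for control and TAL, 0 to 1 for control and TAL-ADH and 0 to 7 for TAL and TAL-ADH.

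Over the alternatives, values of named genes other than TAL1 and ADH1 kept their side of the threshold in 3116 fits, lost a call in 425, gained one in 5, and turned the direction of a called gene in 1. Those of TAL1 and ADH1 lost a call in 16 fits and gained one in 7. Directions of genes not called were not counted. The example genes chosen after their values were seen were not refitted. A slide term beside the 6 group means could not be fitted, the scan partition was the same as the slide, and no gene had several probes to choose between, so these alternatives were not run.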

Other observations

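The tests of the 2 patterns weighed here were chosen after the results were seen. A mating pheromone gene, MF(ALPHA)2, was higher by 3.15 ± 0.39 log2 (SE, n = 2 against 2) in the arrays labelled TAL 0 mM than in the control strain, and furfural raised it in the control strain by 1.85 ± 0.39. In the arrays labelled TAL-ADH 70 mM against TAL 70 mM, the hexose transporter gene HXT13 was at least 7.11-fold higher and HXT11 at least 6.24-fold lower. These genes were chosen after their values were seen.

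Comparisons across the labels, also chosen after the data were seen, put numbers on the 2 sets of arrays. By limma, TAL-ADH 70 mM and control 0 mM, which shared a slide, differed in 2 genes, with 163 at unadjusted p under 0.05. TAL 0 mM and control 70 mM differed in 947 genes, 649 higher and 298 lower.

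Probes that stood on the 4 arrays of a slide above all 8 others by at least 1 log2 numbered 7 on the slide of control 70 mM and TAL 70 mM, 2 on that of TAL 0 mM and TAL-ADH 0 mM, and 0 on the other slide. On the slide of TAL 0 mM and TAL-ADH 0 mM, these were the probes of YDL118W and AI4, so the calls of AI4 may come from the slide. Both gaps are in signal that lay partly below detection, so no size is given. AI4 was detected on none of the 8 other arrays and on 1 of 2 TAL-ADH 0 mM arrays. YDL118W averaged -8.22 on the 8 others, below the lowest level detected on any of them (-8.13). By brightness, the median shift of that slide went from 0.285 in the dimmest genes to -0.188 in the brightest, over 5 classes of equal size. Relative to the bright spike-ins, the 2 dim ones lay higher on that slide (-7.99 to -7.22 log2) than on the slide of control 0 mM (-8.96 to -8.60) but overlapped the slide of control 70 mM (-7.98 to -7.41), so the gap from all 8 other arrays was -0.58 and the test left the cause open. Taken by themselves, the dim spike-ins were higher on that slide (3.34 to 4.67) than on every other array (at most 3.10), where they lay at a median of 0.0400 log2 above the lowest spike-in, and RNA added to every sample does not follow strain or dose. On that slide 1 of the 2, a107, stood at 4.05 to 4.67, clear of the lowest spike-in of those arrays (1.85 to 3.25). The bright ones averaged 10.2 to 10.6 on the slide of control 70 mM and 11.6 to 11.9 on that of TAL 0 mM, which bears on the overlap. Elsewhere the dim spike-ins lay near the floor of detection, so these values left the cause of the raised gene probes open.

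No gene was called for furfural over the 3 strains. Of 100 splits of the arrays within strains, 100 called at least as many as the true labels, which could not have come out otherwise because the true labels called 0. The highest split called 285 genes and was the split by run number. A count so far above that of the true labels points to a structure of the samples along the run number, and the labels do not say what the samples of a run share. The absence of calls could come from chance, or from a furfural effect that differs between strains. The tested differences called 622 and 1194 genes, but they use the arrays labelled TAL 0 mM or TAL-ADH 70 mM and compare groups on different slides. They show a difference between the groups as labelled. The labels of the TAL 0 mM and TAL-ADH 70 mM arrays, if exchanged, could also give the absence of calls.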
